A study of Mus musculus with 8 samples.

How the data were processed

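RNA was sequenced from the hypothalamus of 8 C57BL/6J mice. Per the labels, 4 mice had breathed 7% oxygen in a chamber for 2 hours (hypoxia) and 4 had been kept in room air (normoxia, given as 21% oxygen). RNA was isolated with a column kit, and strand-specific libraries of polyadenylated RNA were made with the TruSeq Stranded mRNA kit, per the labels' protocols.

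The deposited table holds raw read counts per Ensembl gene, 1 column per library. The submitters' processing notes name Trimmomatic, HISAT2 2.0.4, HISAT, SAMtools, featureCounts and DESeq2, and the mouse build mm10. The annotation release, the strand setting of the counting and the treatment of reads that map to several places are not given in the sources used here. Genes that overlap another on the opposite strand, and genes with near-identical copies, are therefore uncertain, which is noted beside only some of their values. Of the genes chosen by the rule below, D7Bwg0826e, Txnip, Ankrd37, Hes5, Neurod1, Mt2, Csrnp1 and Bhlhe40 overlap a gene on the opposite strand. So do Gapdh, Uqcrc2, Pdgfra, Cx3cr1, Zic1, Xist, Nr3c2 and Hif1a. The columns were matched to the libraries by the short names in the sample descriptions. The table has 55487 genes, of which 55141 were matched to a symbol. Coordinates, gene types, lengths and overlaps come from the GENCODE M21 annotation of GRCm38, the assembly of mm10.

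Total counts per library ran from 16994473 (normoxia replicate 3) to 21694383 (normoxia replicate 4). The groups did not differ in total counts beyond their spread (exact permutation test, two-sided p = 0.743). Pairs of libraries within a group had correlations of log2 CPM (counts scaled to a common library total) from 0.976 to 0.992. A chi-square test of each pair's counts gave 4.66 to 38.0 per gene, so each pair differed by more than sampling noise and no library was counted as a repeat of another. The design text calls the 4 libraries of a group biological replicates. The p-values measure the spread between these 8 libraries.

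Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with its minimum count of 10 and minimum total of 15, which left 17047. Libraries were scaled by TMM, and group was the only term of the quasi-likelihood F test, in the form that this version runs by default. Calls had a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. CPM values given per library or as mean ± SD are TMM-scaled, and log2 fold changes are hypoxia relative to normoxia.

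Before the data were examined, 34 gene lists were fixed, of pathways and of cell types or neighbouring regions that the dissected piece could hold. The 32 lists with at least 3 members tested were run with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset inter-gene correlation of 0.01, adjusted by Benjamini-Hochberg over the lists. Beside it stand camera with a correlation estimated from the data, fry, and the number of members called over all genes and adjusted over the list alone.

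The genes named were chosen by a rule also fixed before the data were examined. It takes the 10 largest increases and the 10 largest decreases among called genes with a mean of at least 1 CPM and no overlap between the groups. Genes without a symbol, Gm-numbered models, Rik clones and pseudogenes are counted and not named. It takes from each list the 4 members with the smallest p among those called, or, of a list with none, the member with the smallest p. It always takes Nr3c1, Nr3c2, Crh, Avp, Pomc, Hif1a, Epas1, Fkbp5, Sgk1, Tsc22d3, Vegfa and Fos. This gave 71 genes, of which 1 is not reported here.

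The gene test was tried on simulated data, with 200 of 17047 genes changed in counts drawn from the means and spread of these libraries. Each gene was drawn on its own, without correlation between genes or an outlying library. In a further set drawn the same way, a list raised by a log2 of 0.4 was the only list called by camera. That does not check the list test where members vary together. The gene test called 43% of genes changed by a log2 of 0.5 and 76% of those changed by a log2 of 1 in the right direction. It made 128 calls, 7.03% of them on unchanged genes. Alternatives covered DESeq2 1.42.0, limma-voom, other scalings, filters and thresholds, robust estimation, a block for the replicate number, and each library left out in turn. A newer form of the quasi-likelihood test, and a fit without normoxia replicate 2 and hypoxia replicate 4 together, were added after seeing the data. The GC content and length check used exon lengths and GC from the same annotation. The search for copies of mitochondrial mRNAs used its transcripts, since the genome sequence was not used here.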

Results

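The series asks how low oxygen alters glucocorticoid receptor function, and these libraries record gene expression in the mouse hypothalamus after 2 hours. The hypothalamus is the brain region that starts the hormonal stress response. Polyadenylated RNA was counted per gene in 4 hypoxia and 4 normoxia mice, with 16994473 to 21694383 counts per library. Mitochondrial genes took 4.90 ± 0.0926% of counts in hypoxia and 4.62 ± 0.268% in normoxia (SD, n = 4 each; exact permutation test, two-sided p = 0.114). All 8 libraries had Xist at 584 to 889 CPM and counts of 0 for the Y-linked genes Ddx3y, Uty, Kdm5d and Eif2s3y.

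After 2 hours at 7% oxygen, 156 genes were higher and 210 were lower than in normoxia, of 17047 tested. Of these, 57 rose and 21 fell by at least 2-fold. Genes of the hypoxia-inducible factor (HIF) response and genes that respond to glucocorticoids were among the increases. Genes for the glucocorticoid receptor and for hypothalamic peptides were not among the called genes. As a list, the neuropeptides and hormones were called higher by camera (adjusted p = 0.000532), but not with an estimated correlation (adjusted p = 0.758). Of all genes tested, 2291 (13.4%) had no overlap between the 4 hypoxia and 4 normoxia libraries, where chance gives 2.86% on average. The 366 called genes all belonged to these. Genes that vary together can move the share without overlap away from that average, and its spread over other groupings is not given here. The calls come from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and 3291 genes had an unadjusted p under 0.05. Scaling by library size alone gave 146 higher and 342 lower genes, a larger share of decreases. The number of calls depended on single libraries. It was 693 without hypoxia replicate 4, 675 without normoxia replicate 2, and 26 to 50 without any of the other 6. The excess of decreases did not hold in those 6 fits, which had 24 to 42 higher and 2 to 8 lower genes.

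The largest increase was that of Depp1, a target of FOXO transcription factors on chromosome 6 (116650609 to 116652794, mm10). It rose from 0.528 ± 0.172 CPM in normoxia to 14.2 ± 4.83 CPM in hypoxia (SD, n = 4 each), a log2 fold change of 4.71 ± 0.35 (SE; edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.000995). Adm, which encodes the vasodilator peptide adrenomedullin, rose from 1.03 ± 0.257 to 7.29 ± 2.93 CPM (log2 2.80). Maff, a small MAF transcription factor, rose by a log2 of 2.53 and Klrg2, a lectin-like receptor gene, by 3.18. Txnip, whose product inhibits thioredoxin and glucose uptake, went from 26.6 ± 3.66 to 92.1 ± 24.4 CPM (log2 1.79). Tmem252 (log2 2.29) and Tnfrsf4, a tumour necrosis factor receptor family member (log2 2.07), rose from under 1 CPM. The increases also held D7Bwg0826e (log2 3.19), an unclassified transcript on chromosome 7 (44894305 to 44898099). It overlaps Fuz on the opposite strand, as Txnip overlaps Gm15441, so these values are uncertain if the counting ignored strand.

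Among the decreases, Hes5, a target of Notch signalling, fell from 13.4 ± 0.744 to 5.97 ± 1.17 CPM (SD, n = 4 each; log2 −1.16 ± 0.13, SE; edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.0069). Id3, an inhibitor of basic helix-loop-helix transcription factors, fell from 24.9 ± 1.31 to 11.9 ± 2.09 CPM (log2 −1.07). Neurod1, a neuronal transcription factor of that class, fell from 4.93 ± 1.01 to 1.78 ± 0.368 CPM (log2 −1.46). Hes5 overlaps Gm20421 and Neurod1 overlaps Gm26755 on the opposite strand, so both values are uncertain if the counting ignored strand. The transcription factor gene Hhex had a log2 change of −1.13. Clec2d and Tmem170 each had −1.10. AI429214 had −1.05, Depdc7 −1.49 and the death receptor gene Tnfrsf25 −1.99. The largest decrease, Cnpy1 (log2 −3.59 ± 0.76), had an uneven normoxia group, at 3.24, 1.06, 7.64 and 2.95 CPM against 0 to 0.649 CPM in hypoxia. En2 and Fzd10, genes of the midbrain and hindbrain border as Cnpy1 is, had −1.17 and −1.19 (adjusted p = 0.194 and 0.138). Both were picked after their values were seen and belong to no fixed list. Within normoxia all 3 were lowest in replicate 2. Of the 44 named genes that were called, 16 were called with each library left out in turn, among them Depp1, Klrg2, Maff, Txnip, Hes5 and Id3. Another 21 were called in none of the 6 fits that left out a library other than normoxia replicate 2 and hypoxia replicate 4, among them Sgk1, Tnfrsf4, Cnpy1, Tnfrsf25, Depdc7, Hhex, Clec2d, Tmem170 and AI429214. The rest of the 21, named below, were Hk2, Gapdh, Klf6, Ier3, Stat2, Irf9, Bhlhe40, Trp53inp1, Gjb6, Pdgfra, Slco1a4 and Kcnj8. Adm, Tmem252, Ldha and Errfi1 were called in 3 of the 8 fits with 1 library left out.

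**Figure D1:**
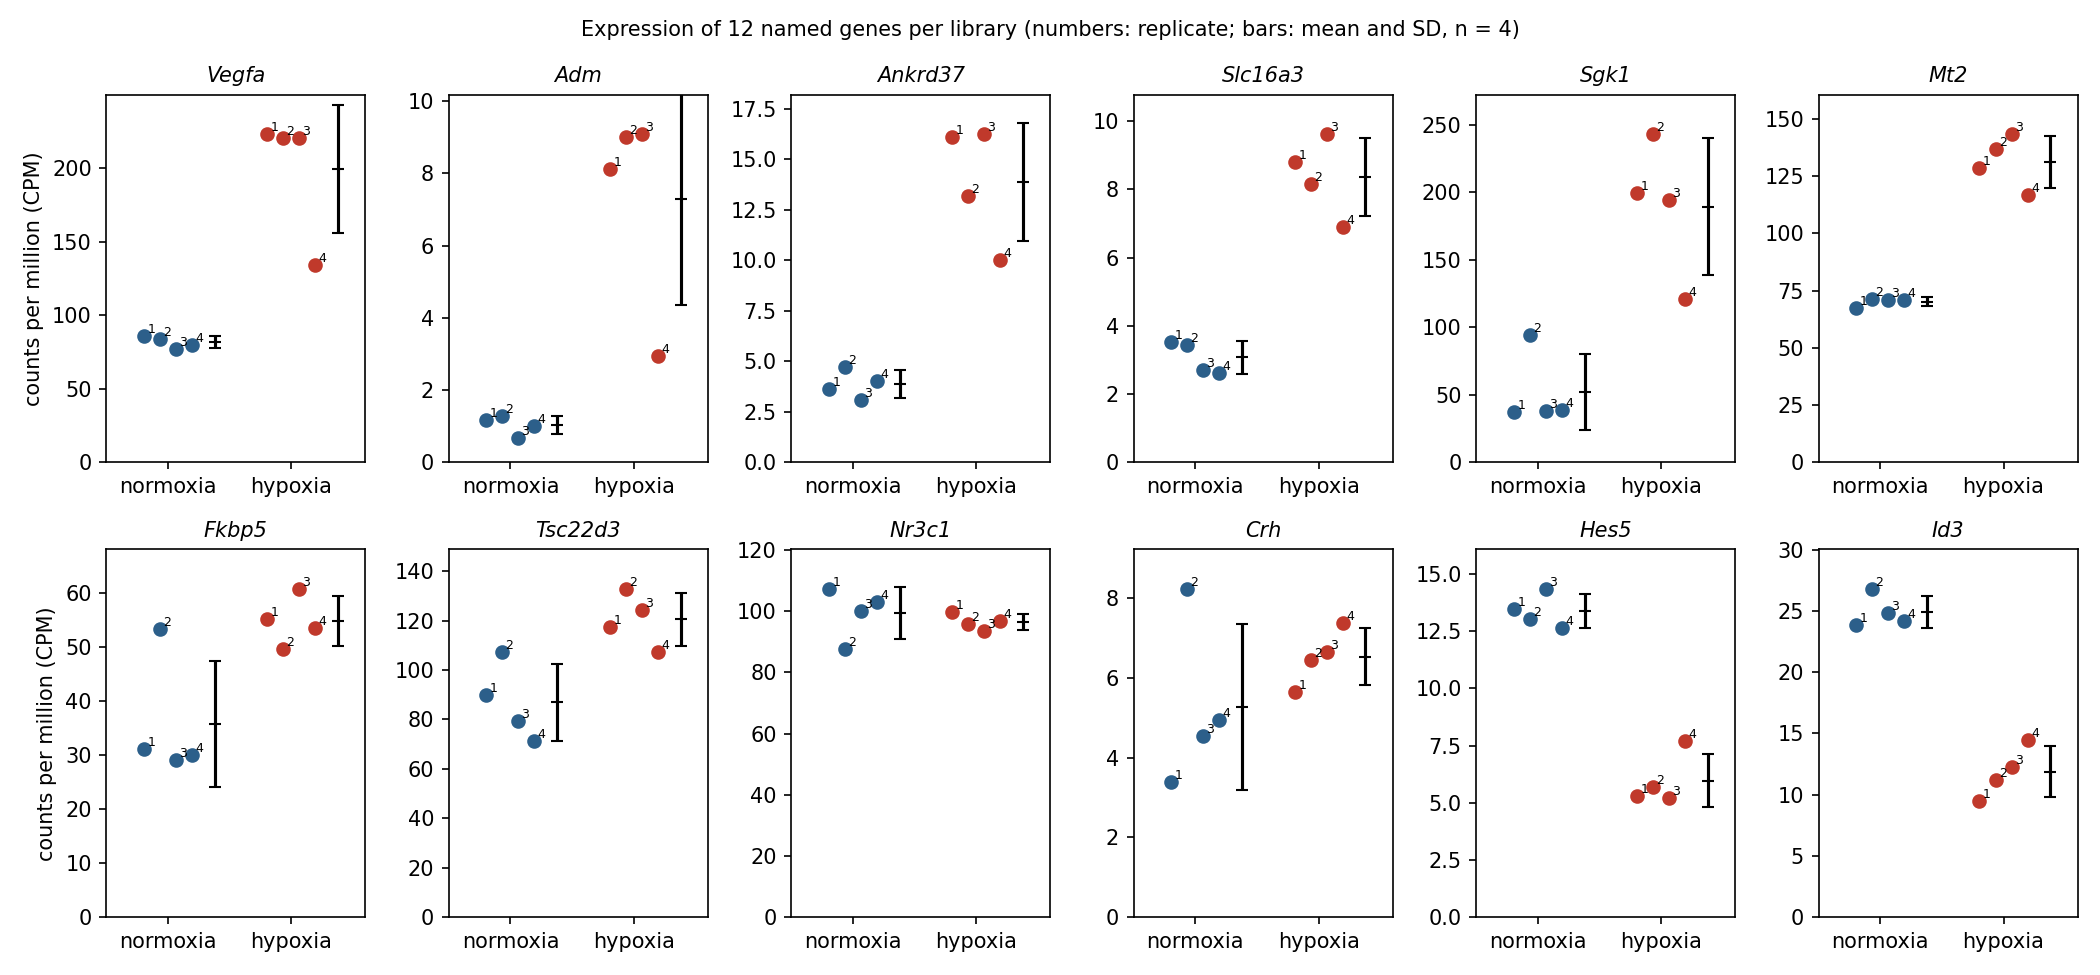
CPM (linear axis from 0) of 12 named genes in each normoxia (blue) and hypoxia (red) library; points are libraries with their replicate number and bars are mean and SD of 4. Sgk1 lay at 94.5 CPM in normoxia replicate 2 against 37.3 to 38.6 in the other normoxia libraries, and Vegfa at 134 CPM in hypoxia replicate 4 against 220.3 to 223 in the other hypoxia libraries.

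Of 35 HIF target genes outside glycolysis, 12 were higher and 0 lower over all genes tested, and 23 were higher adjusted over the list alone. Hypoxia replicate 4 lay below the rest of its group in this list, at a mean log2 CPM of 0.03 relative to the 8 libraries against 0.31 to 0.35, and without it 19 members were called higher. It was 15 without normoxia replicate 2 and 4 or 5 without any of the other 6 libraries. Vegfa, which encodes the vascular growth factor VEGF-A, rose from 81.6 ± 4.18 to 199.6 ± 43.5 CPM (SD, n = 4 each; log2 1.29 ± 0.15, SE; edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.0069). Slc16a3, a lactate transporter, rose by a log2 of 1.44 and Ppp1r3c, a regulatory subunit that promotes glycogen storage, by 1.05. Ankrd37 rose from 3.87 ± 0.69 to 13.9 ± 2.93 CPM (log2 1.84), and it overlaps Lrp2bp and Ufsp2 on the opposite strand. The median log2 change of the list was 0.29 (camera, adjusted p = 1.49e-13). The call was lost at adjusted p = 0.292 with an estimated correlation, and fry gave an adjusted p of 0.0107. The transcripts of the HIF subunits themselves were not called, with Hif1a at a log2 of 0.09 and Epas1 at 0.00.

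Of 20 glycolysis enzymes, 4 were higher and 0 lower, and 9 were higher adjusted over the list alone. Without any 1 of the libraries other than normoxia replicate 2 and hypoxia replicate 4, edgeR called 1 or 2. Pfkfb3, which makes the activator of phosphofructokinase, rose from 54.2 ± 4.46 to 101 ± 14.9 CPM (log2 0.90), and Hk2, a hexokinase, rose by a log2 of 0.91. Ldha, which makes lactate dehydrogenase A, rose from 168 ± 9.36 to 227 ± 13.4 CPM (log2 0.43). Gapdh rose by a log2 of 0.58 from 22.9 ± 1.36 CPM, and Gapdh and Ldha have many pseudogene copies, so their levels are uncertain. The list had a median log2 change of 0.10 (camera, adjusted p = 2.43e-05, and fry, adjusted p = 0.0107). The camera call was lost at adjusted p = 0.292 with an estimated correlation.

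All 27 glucocorticoid-responsive genes tested had a positive log2 change, with a median of 0.69. Of these, 9 were called higher over all genes and 23 adjusted over the list alone. The 9 include Ddit4, which is also among the called HIF targets, and Gjb6, which is also in the astrocyte list. These libraries measure RNA only, so the list cannot tell glucocorticoid action from another effect of low oxygen. Mt2 and Mt1, which encode metal-binding metallothioneins, rose from 70.2 ± 1.97 to 131 ± 11.4 CPM (log2 0.90) and from 116 ± 6.95 to 166 ± 6.13 CPM (log2 0.52; SD, n = 4 each). Mt2 overlaps Gm45774 on the opposite strand, so its value is uncertain if the counting ignored strand. Arrdc2, an arrestin-domain gene, rose by a log2 of 1.46 and Errfi1, an inhibitor of epidermal growth factor receptor signalling, by 0.73. Sgk1, the serum- and glucocorticoid-regulated kinase, rose from 52.1 ± 28.3 to 189 ± 50.5 CPM (log2 1.87 ± 0.33, SE; edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.0301). Fkbp5, a co-chaperone that restrains the receptor, had a log2 change of 0.61 and an adjusted p of 0.114. Tsc22d3, the glucocorticoid-induced leucine zipper, had 0.47 and an adjusted p of 0.0768. Camera gave an adjusted p of 1.47e-20 for the list, and the call was lost at adjusted p = 0.292 with an estimated correlation. The adjusted p by fry was 0.0107. Normoxia replicate 2 lay above the rest of its group in this list, at a mean log2 CPM of 0.06 relative to the 8 libraries against −0.65 to −0.58. Without that library, 22 members were called higher. It was 13 without hypoxia replicate 4 and 3 or 4 without any of the other 6. Of the 35 splits of the 8 libraries into groups of 4, 2, the real one among them, gave a camera p at least as small as the real one.

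The receptor genes and the peptides of the stress axis were not called. Nr3c1, which encodes the glucocorticoid receptor, was at 96.6 ± 2.55 CPM in hypoxia and 99.5 ± 8.42 in normoxia, and Nr3c2, the mineralocorticoid receptor gene, at 37.7 ± 1.83 and 36.5 ± 7.47 (SD, n = 4 each). Of the 13 tested genes for the receptor and its regulators, 0 were called over all genes and 0 adjusted over the list alone, with 3291 of all genes at an unadjusted p under 0.05 (camera, adjusted p = 0.437). In the leave-one-out fits, 1 member was higher without normoxia replicate 2 and 0 without any other library. Crh, the releasing hormone that starts the stress axis, had a log2 change of 0.31 ± 0.24 (SE), Avp, the vasopressin gene, 0.10 ± 0.24, and Pomc, the precursor of adrenocorticotropic hormone, 0.43 ± 0.20. Of 26 neuropeptides and hormones, 23 had a positive log2 change, with a median of 0.25, and 0 were called by edgeR over all genes or adjusted over the list alone. Normoxia replicate 2 was the lowest of the 8 libraries in 18 of the 26, Avp, Oxt, Hcrt, Pmch and Pomc among them, and without it the median was 0.17 and 1 member was higher. Camera called the list (adjusted p = 0.000532), and the call was lost at adjusted p = 0.758 with an estimated correlation. Its member with the smallest p, the neurotensin gene Nts, had a log2 change of 0.39 (adjusted p = 0.0984).

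**Figure D2:**
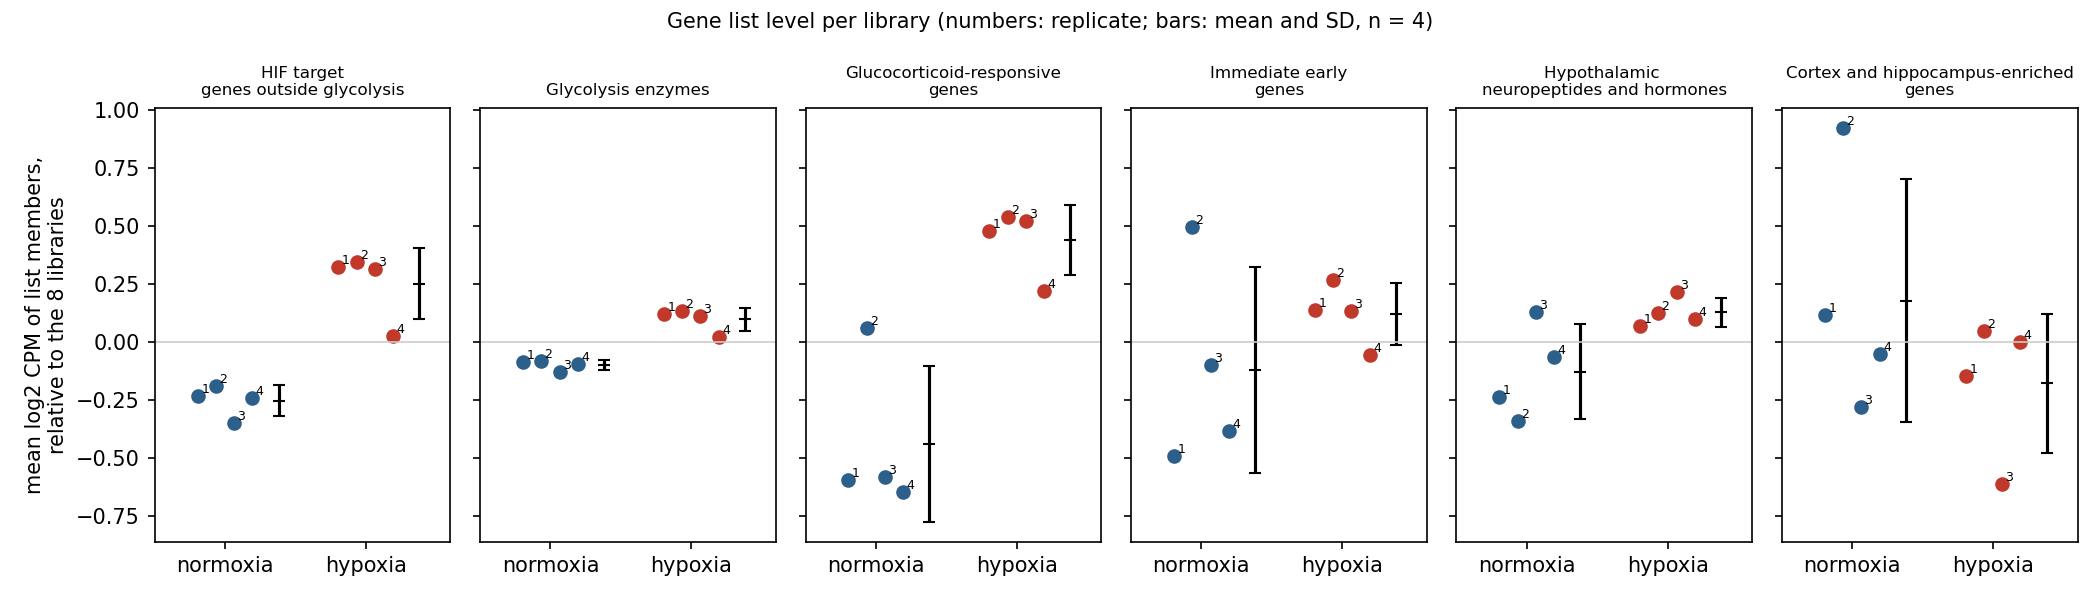
Mean log2 CPM of the members of 6 gene lists, relative to the mean of the 8 libraries, in each normoxia (blue) and hypoxia (red) library; points are libraries with their replicate number and bars are mean and SD of 4. HIF targets lay at 0.03 to 0.35 in hypoxia and −0.35 to −0.19 in normoxia, and in glucocorticoid-responsive genes normoxia replicate 2 lay at 0.06.

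Immediate early genes, which neurons switch on within minutes of stimulation, went both ways. Of 35 tested, 5 were higher and 1 was lower over all genes, and 5 and 2 adjusted over the list alone (camera, adjusted p = 0.0527). Csrnp1 rose by a log2 of 1.21 and Ier3 by 1.09, while Klf6 had a log2 change of −0.48. Fos, a marker of neuronal activation, had 0.39 ± 0.40 (SE; adjusted p = 0.638). Normoxia replicate 2 was at 0.49 in this list, against −0.49 to −0.10 in the other normoxia libraries, and without it 8 members were higher and 1 was lower. Without any of the other libraries except hypoxia replicate 4, 2 were higher and 0 lower. With 1 library left out, camera called the list in 4 of 8 fits (adjusted p from 0.000219 to 0.334; without hypoxia replicate 1, 3 or 4, or normoxia replicate 2).

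Among other stress and metabolic lists, camera called 0 by its adjusted p. In the ATF4 list (14 tested, adjusted p = 0.977), the pseudokinase gene Trib3 rose by a log2 of 1.64. In the circadian clock list (18 tested, 0.346), the repressor genes Ciart and Bhlhe40 rose by a log2 of 1.30 and 0.69, and Bhlhe40 is also a HIF target. In the p53 list (13 tested, 0.624), Trp53inp1 rose by a log2 of 0.51. In the interferon list (17 tested, 0.13), Stat2 and Irf9, members of the same signalling complex, had −0.38 and −0.60. In the 8 leave-one-out fits, Trib3 and Ciart were called in 7, and Bhlhe40, Trp53inp1, Stat2 and Irf9 in 2. No member was called over all genes in the lists of heat shock proteins (15 tested, 0.974), endoplasmic reticulum chaperones (14 tested, 0.338), nuclear-encoded respiratory subunits (32 tested, 0.346), mitochondrially encoded mRNAs (13 tested, 0.0638), inflammatory genes (11 tested, 0.977), cholesterol synthesis (20 tested, 0.127) or ribosomal proteins (30 tested, 0.121). Among the members with the smallest p in these lists, Chordc1 had a log2 change of −0.36, Pdia4 −0.23, Uqcrc2 0.09, mt-Nd1 0.23, Nfkbia 0.87 and Rps20 0.15. With 1 library left out, camera called the mitochondrial list in 2 of 8 fits (without hypoxia replicate 3, adjusted p = 0.0006, or normoxia replicate 1). It called the interferon list without hypoxia replicate 2 (0.0218), and without normoxia replicate 2 the cholesterol (0.00108), ribosomal (0.00384) and respiratory (0.0422) lists. Among these lists without a called member, edgeR called some with 1 library left out. Without normoxia replicate 2 it called 2 inflammatory and 2 mitochondrial genes higher and 2 cholesterol genes lower, and without hypoxia replicate 4 it called 1 inflammatory gene higher and 1 heat shock gene lower. Of the mitochondrial mRNAs, 6 varied by more than 10-fold between libraries of both groups, so that list level is uncertain.

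Camera called 0 of the 15 lists of cell types and neighbouring regions. In the astrocyte list (15 tested, adjusted p = 0.13), the connexin gene Gjb6 rose by a log2 of 0.34. Pdgfra rose by 0.26 and belongs to the oligodendrocyte precursor (10 tested, 0.346) and meningeal fibroblast (12 tested, 0.235) lists. In the endothelial list (15 tested, 0.167), the transporter gene Slco1a4 had −0.48, and in the mural cell list (12 tested, 0.295), the potassium channel gene Kcnj8 rose by 0.98. Adm was the called member of the ependymal and tanycyte list (13 tested, 0.346) and Neurod1 that of the cortex and hippocampus list (11 tested, 0.346). In the 8 leave-one-out fits, Adm was called in 3, Neurod1 in 5, and Gjb6, Pdgfra, Slco1a4 and Kcnj8 in 2. No member was called over all genes in the lists of neurons (15 tested, 0.235; Gad2 0.22, and 1 member higher without normoxia replicate 2), oligodendrocytes (15 tested, 0.346; Aspa −0.31), microglia (15 tested, 0.797; Cx3cr1 −0.15), choroid plexus (9 tested, 0.889; Clic6 0.45), pituitary (7 tested, 0.346; Pomc 0.43), thalamus (12 tested, 0.125; Zic1 −0.27), striatum (12 tested, 0.0527; Rgs9 0.47) or red blood cells (5 tested, 0.346; Hbb-bt −0.39). In 2 lists of neighbouring regions all members differed in the same direction between the groups without the list passing the test. All 12 striatum genes had a positive log2 change (median 0.32) and 0 of 12 thalamus genes did (median −0.49). Leaving out 1 library at a time, the medians ran from 0.19 to 0.53 and from −0.77 to −0.01. With 1 library left out, camera called the striatum list in 4 of 8 fits (adjusted p from 0.00337 to 0.282; without hypoxia replicate 1 or 2, or normoxia replicate 2 or 4) and the thalamus list in 2 of 8 (0.00435 to 0.729; without hypoxia replicate 1 or normoxia replicate 2). It called the endothelial (lowest adjusted p 0.0146) and oligodendrocyte (0.0195) lists without hypoxia replicate 2 or normoxia replicate 2, and the meningeal fibroblast list without hypoxia replicate 2 (0.0142). The leukocyte list had 1 member tested, Cd79a (log2 −0.43). Slc17a7, a cortical transporter gene, was at 384 CPM in normoxia replicate 2 and 7.92 to 80.3 CPM in the other 7 libraries. Prl and Gh, pituitary hormone genes, were at 40.4 and 38.9 CPM there, and at 28.6 and 11.7 CPM in hypoxia replicate 4.

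**Figure D3:**
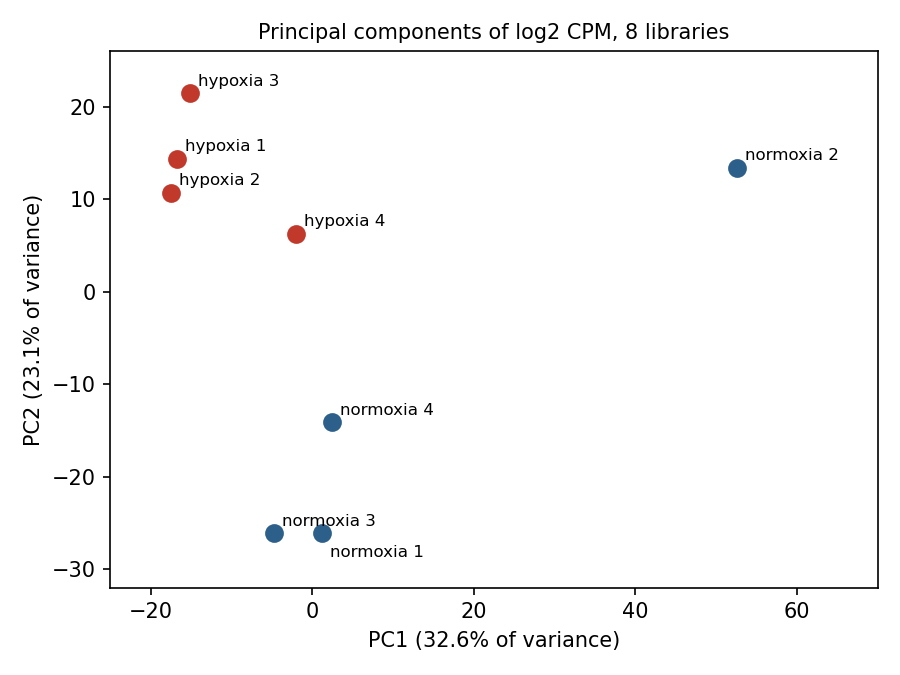
Principal components of log2 CPM, with each point a library (red hypoxia, blue normoxia) and the share of variance on each axis. Normoxia replicate 2 lay at 52.6 on the first component (32.6% of variance), and the other 7 libraries between −17.5 and 2.43.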

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

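The tests of the 2 libraries and of the mitochondrial mRNAs were chosen after the values were seen, and so was the count of splits for the 366 genes and the 4 lists. The split counts for single lists, and the tests of the zinc finger genes, were set before their results were seen. Of 212 groups of 4 values examined, 21 held a library far from the other 3, where chance gives about 1 in 20 for independent values. Many of these groups share genes or libraries, as Vegfa and its list do, and some genes were chosen from these data. That rate is therefore no baseline for the 21. Hypoxia replicate 4 was the far library in 8 and normoxia replicate 2 in 4.

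Of the 156 genes called higher, 125 were lowest in hypoxia replicate 4 among the hypoxia libraries, and of the 210 called lower, 162 were highest there; the others were not. Vegfa was at 134 CPM against 220.3 to 223, Adm at 2.94 against 8.12 to 9.08, Ppp1r3c at 66.7 against 88.1 to 91.7, Nfkbia at 23.1 against 34.4 to 36.4 and Bhlhe40 at 82.4 against 118 to 125. Clec2d lay higher, at 2.45 against 1.35 to 1.45 and Klf6 at 35.5 against 29.4 to 30.0. The HIF target list was at 0.0253 against 0.314 to 0.347. Its position between normoxia replicates 1, 3 and 4 (0) and the other hypoxia libraries (1) was 0.497 for HIF targets and 0.738 for glucocorticoid-responsive genes.

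Normoxia replicate 2 lay above the other normoxia libraries in Sgk1 (94.5 CPM against 37.3 to 38.6), Fkbp5 (53.3 against 29.0 to 31.0), Xist (889 against 584 to 606) and the glucocorticoid-responsive list (0.0625 against −0.646 to −0.583). Its HIF targets give limited evidence against a swap with, or a sample from, the hypoxia group. On the scale from the other normoxia libraries (0) to the hypoxia mean (1) they lay at 0.162, with a bootstrap interval from −0.177 to 0.478, while glucocorticoid-responsive genes lay at 0.64. This interval takes the members as independent. The interval of hypoxia replicate 4 (0.351 to 0.604) is on another scale, so the overlap of the 2 decides nothing. Each split that exchanged normoxia replicate 2 with a hypoxia library gave 0 called genes, against 366 for the real grouping. Over all genes this argues against a swap. For glucocorticoid-responsive genes alone, the split of normoxia replicate 2 with hypoxia replicates 1, 2 and 3 gave a smaller camera p than the real one. A sample from the hypoxia group without an exchange was not tested by splits. Cortical or hippocampal tissue in the dissected piece cannot be told apart from a difference between animals: that list of 11 genes was higher by 0.996 on the log2 scale, and no profile of that tissue was at hand to say how much it would raise the glucocorticoid-responsive genes. In the same library 25 of 35 immediate early genes lay above all other normoxia libraries, and no biological explanation was tested.

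Of 13 mitochondrial mRNAs, 6 neighbours (mt-Co2, mt-Atp8, mt-Atp6, mt-Co3, mt-Nd3 and mt-Nd4l) varied by more than 10-fold between libraries, with mt-Co2 from 4.16 to 379 CPM, in both groups. Mitochondrial RNA content differing between animals is argued against, since the other 7 varied by at most 1.84-fold. Reads shared with nuclear copies, such as the pseudogenes Gm28661 and Gm10925 on chromosome 1, may be lost differently between libraries. At the limit tried first, at least 50% of an mRNA's 50-mers in another transcript, 5 of the 6 and 2 of the other 7 had a copy (Fisher's exact p = 0.103), which does not separate them. Raising the limit to 90% after that result gave 5 of 6 and 0 of 7 (Fisher's exact p = 0.00466), which as a second try settles nothing, and no transcript covers the stretch where a copy of mt-Atp8 would lie, so this explanation stays open.

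Smaller departures follow as values. Normoxia replicate 1 had Mt2 at 67.2 CPM against 70.8 to 71.5, Csrnp1 at 3.67 against 4.81 to 4.84 and Kcnj8 at 4.23 against 2.92 to 3.13. Normoxia replicate 4 had Ciart at 8.63 CPM against 7.00 to 7.12. Hypoxia replicate 2 was above its group in the respiratory subunit (0.063), astrocyte (0.104) and oligodendrocyte (0.313) lists. Normoxia replicate 3 was below its group in the neuron (−0.13) and microglia (−0.252) lists.

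The real grouping gave 366 genes, and each of the other 34 splits of the 8 libraries gave 0. So 1 of 35 splits gave as many, the smallest share that 35 splits can give. As this count was chosen after the values were seen, it does not by itself exclude chance. The number of lists gives no evidence against chance, since 35 of the 35 splits gave 4 lists or more with the preset correlation, up to 13. For single lists, 1 of the 35 splits gave a camera p as small for HIF targets and 1 for glycolysis enzymes, where the smallest p of the other splits were 9.17e-12 and 8.01e-05. For glucocorticoid-responsive genes it was 2 of 35, and chance is not excluded by this count. The split with the smaller p (3.21e-22) put normoxia replicate 2 with hypoxia replicates 1, 2 and 3. For neuropeptides it was 7 of 35 (smallest other p 1.28e-10), and chance is not excluded.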

How the results depend on the processing

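The newer quasi-likelihood form and the fit without normoxia replicate 2 and hypoxia replicate 4 together were chosen after seeing the data. All 366 calls kept their direction in each alternative that tested them, and the 348 tested at a mean CPM of at least 1 did so there. The number of calls did not keep its size. DESeq2 called 958 genes (362 higher, 596 lower), with 356 of the 366 among them; the cause was not tested. An adjusted p under 0.01 left 26 (24 higher, 2 lower), and a log2 change of at least 0.5 left 196 (107 higher, 89 lower), by construction. Library size scaling gave 342 lower genes. Its median log2 change over all genes was −0.03, against −0.01 with TMM. Leaving out 1 library in turn gave 26 to 693 genes (24 to 329 higher, 2 to 457 lower). The highest total came without hypoxia replicate 4, then 675 without normoxia replicate 2, and the other 6 gave 26 to 50. Leaving out both of those libraries gave 1195 genes (456 higher, 739 lower), and Fkbp5 (log2 0.88), Tsc22d3 (0.64) and Nfkbia (1.22) were then called. With the replicate number as a block, 21 genes were called (20 higher, 1 lower) and 7 lists. Samples with the same number had correlations of their deviations of 0.0375, −0.105, 0.043 and −0.028. These show no sign that the numbers pair the samples, but so few values cannot exclude it. Camera called 4 lists, 0 with an estimated correlation (adjusted p = 0.292 for HIF targets, glycolysis enzymes and glucocorticoid-responsive genes, 0.758 for neuropeptides), 3 by fry, 4 to 12 with 1 library left out (12 without normoxia replicate 2, 9 without hypoxia replicate 2, 7 without hypoxia replicate 1) and 8 without both. The 4 lists kept their call with each library left out.

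Reversals touched genes and lists that were not called, and the cause was not tested. With 1 library left out, log2 changes ran from −0.117 to 0.11 for Xist, −0.0943 to 3.15e-05 for Nr3c1, −0.0607 to 0.176 for Nr3c2, −0.0798 to 0.274 for Avp and −0.0177 to 0.0575 for Epas1. Epas1 was at −0.0236 with library size scaling, and Xist at 0.0893 without both libraries. Some lists turned direction with 1 library left out. Their camera adjusted p is given over all 8 such fits, turned or not. It ran from 0.533 to 0.971 for heat shock proteins, 0.646 to 0.996 for ATF4 genes and 0.643 to 0.942 for inflammatory genes. For oligodendrocytes it ran from 0.0195 to 0.696, for microglia from 0.108 to 0.952 and for choroid plexus from 0.529 to 0.971. For red blood cells it ran from 0.105 to 0.925. The oligodendrocyte list turned only without normoxia replicate 1 (0.638). The red blood cell list turned only without hypoxia replicate 1 (0.925). Further turns came for heat shock proteins by fry (0.903), for ATF4 genes (0.89) and inflammatory genes (0.853) with the replicate block, and for inflammatory genes with RLE scaling (0.987). Without both libraries, heat shock proteins (0.769), microglia (0.855) and choroid plexus (0.544) turned. At this depth and spread the simulated test found 43% of changes of log2 0.5, so small changes can be missed.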

Other observations

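The genes in this part were chosen after their values were seen, and the zinc finger set was formed from the data. The genes named singly belong to no list that was tested. Their calls with 1 library left out are not given here, and in those fits the total of lower genes ran from 2 to 457. Jag1, which encodes a Notch ligand, fell from 13.9 ± 0.659 to 7.23 ± 1.89 CPM (SD, n = 4 each; log2 −0.94, edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.0284). Lfng, a glycosyltransferase that modifies Notch, rose from 26.9 ± 1.58 to 39.8 ± 4.27 CPM (log2 0.57).

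The splicing kinase genes Clk1 and Clk4 fell from 142 ± 15.7 to 69.9 ± 21.7 CPM (log2 −1.02) and from 77.4 ± 3.13 to 50.5 ± 6.46 CPM (log2 −0.61). Clk1 was at 102 CPM in hypoxia replicate 4 against 56.0 to 60.7 in the other hypoxia libraries. The RNA-binding protein gene Rbm5 had a log2 change of −0.43, and Mettl3, a catalytic subunit of the RNA methyltransferase for adenosine, −0.59. Among the increases, F3, which encodes tissue factor, rose from 51.3 ± 4.67 to 106 ± 17.8 CPM (log2 1.04), and Arrdc3, an arrestin-domain gene, by a log2 of 0.84.

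Of 357 protein-coding genes named Zfp with a number, 279 had a log2 change below 0, with a median of −0.18, and 23 were called lower against 3 higher. Without hypoxia replicate 4 the count was 67 lower and 3 higher, and without normoxia replicate 2 it was 33 and 3. Without any of the other 6 libraries edgeR called 0 lower and 0 higher. These 23 were among the 210 decreases, while the set made up 2.09% of the genes tested. GC content and gene length are argued against as the whole cause, since the median was −0.172 before and −0.139 after removing both trends, with a bootstrap interval from −0.177 to −0.107. Chance is not excluded: 2 of 35 splits gave a camera p as small, and the split that exchanged hypoxia replicate 4 with normoxia replicate 1 gave 2.09e-15. A lower output of short-lived transcripts may underlie the pattern as a hypothesis, and no half-lives were at hand to test it.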
